A study of Mus musculus with 47 samples.

How the data were processed

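RNA was measured in 47 liver samples in 14 groups, each assigned from the sample titles. The extract protocol names an RNeasy Plus mini kit and Illumina libraries and sequencing by Novogene. The authors deposited a table of TPM values for 24411 genes, of which 6000 are at 0 in every library. Every column of it sums to the same total, so the authors scaled each library per transcripts and the values hold no read depth. The authors also deposited 6 tables of their own comparisons with log2 fold changes, taken here as given, and with the authors' p-values, raw and adjusted. The submitters' processing notes name the mm10 build, STAR (version not given), R 4.1.3 and DESeq2 1.34.0 without a role or order, so DESeq2 is credited to the authors only as a named tool. The quantifier and the gene annotation are not given in the sources used here. The TPM table holds no mitochondrial genes, and some gene names in 3 of the authors' deposited tables had been turned into dates (21, 22 and 22 names), which were left out.

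Each TPM column was matched to a sample through the sample's description, which holds the column name, and 0 columns of sample values were left unmapped. No pair of libraries held identical values (0 pairs, highest correlation 0.99357). The 10 most abundant genes took 18.5 to 24.6% of a library. Because depth is unknown, the precision of each value was taken from the spread between libraries, as SD over 3 or 4 libraries per group. Gene positions come from the GENCODE annotation of GRCm38, the build that mm10 names.

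The design, the gene lists, the rule for which genes are named and the alternatives were fixed before the data were examined. Values were tested in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), with the variance trend on mean expression, two-sided. Genes with a mean TPM of at least 1 over the libraries of a fit were tested, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Each knockout was compared with its own floxed controls. The 4 groups of the dexamethasone experiment entered a single fit of group means, with contrasts for the treatment in each genotype, for the knockout with vehicle and for the interaction. Differences of knockout effects between days, and between the double and the Hdac3 knockout at day 15, were tested as differences of contrasts. Single levels were also compared by exact permutation of the libraries, two-sided, over all splits. With 3 against 3 libraries the smallest p this exact test can give is 0.1, and with 3 against 4 or 4 against 4 it is 0.0286.

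The 37 gene lists hold 779 entries on metabolism, nuclear receptor targets, stress, sex bias and zonation, the clock, the corepressor complex and markers of liver cell types. Of the entries, 757 matched by symbol, 1 through a synonym and 21 did not match. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Members past the threshold were counted over all genes and after adjusting over the list alone. Lists are described where camera passed the threshold or where they bear on gluconeogenesis, glucocorticoid response, the clock, lipid synthesis, PPARα or other cell types, and not every list of every comparison is printed. The genes named are the targets and 16 preselected genes, the 8 largest changes each way among genes whose groups do not overlap and whose higher mean is at least 5 TPM, and up to 4 members per described list. Predicted gene models and pseudogenes were left out of the largest changes.

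The alternatives were a pseudocount of 0.1, no filter on low values, TPM rescaled per library by median-of-ratios factors (0.703 to 1.2), all libraries in a single fit, the replicate number as a block, and each library left out in turn. Fits without 2 libraries that stood apart, with rescaling, were added after the data had been seen. Bootstrap intervals (95%, 2000 draws) resample genes, which are not independent replicates. The pipeline was tested on simulated data in which 66 or 67 genes were given each of 3 sizes of change. Of genes changed by 1 on the log2 scale it called 94% at day 5 and 98.5% at day 15 of the double knockout, 73.1% for Ncor1, 64.2% for Ncor2, 95.5% for Hdac3, 82.1% and 80.6% for dexamethasone in controls and double knockouts and 58.2% for the interaction. False calls made up 0.8 to 7.49% of the calls. A gene that was not called in the smaller cohorts therefore need not be unchanged.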

Results

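RNA from 47 mouse liver samples was sequenced, and the deposited table gives TPM, transcript abundance scaled to the same total in each library, for 24411 genes named by symbol. All mice were male, carried floxed alleles and were killed at zeitgeber time 10. An adeno-associated virus (AAV) carried either eGFP, for the controls, or Cre recombinase, for the hepatocyte knockouts. Ncor1 and Ncor2 encode the nuclear receptor corepressors NCoR1 and NCoR2 (SMRT), and Hdac3 encodes the histone deacetylase of the same complex. The double knockout of Ncor1 and Ncor2 was sampled 5 days after AAV (3 knockout, 4 control libraries) and 15 days after it (4 and 4). The single knockouts were sampled at day 15, with 3 and 3 libraries for Ncor1, 3 and 3 for Ncor2, and 4 and 4 for Hdac3. In a separate day 5 experiment, double knockout and control mice received 1 mg/kg dexamethasone, a synthetic glucocorticoid, or vehicle and were killed 2 h later (3 libraries in each of the 4 groups).

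Read totals per library are not given in the sources used here, and TPM does not hold them. Between 10079 and 12033 genes per library reached 1 TPM. The labels number the replicates without stating that they are separate animals, so p-values measure the spread between these samples. Levels below are mean ± SD in TPM, knockout (or dexamethasone) first. Log2 changes, ± standard error, are on log2(TPM + 1), which understates changes of genes with low levels. Adjusted p-values are from limma with Benjamini-Hochberg adjustment, and rose, fell and changed refer to an adjusted p under 0.05. For gene lists, camera asks whether the members rank apart from the other genes, and counts are also given adjusted over the list alone. Positions are in the GRCm38 build.

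How far each target was lost was read from its own transcript. The SD of each percentage holds only the spread of the knockouts, over the control mean, and leaves out the spread of the controls. Ncor1 (chromosome 11, 62316426 to 62458541) stood at 45.9 ± 8.11% of control in the double knockout at day 5 (n = 3) and at 33.8 ± 6.95% at day 15 (n = 4). Ncor2 (chromosome 5, 125017153 to 125179219) stood at 44.9 ± 6.65% and 44.6 ± 13.2% in those livers. In the vehicle-treated double knockout Ncor1 stood at 30.4 ± 14.1% and Ncor2 at 38.2 ± 12% (n = 3). In the Ncor1 knockout, Ncor1 was 8.53 ± 1.91 against 19.9 ± 2.5 TPM (n = 3 and 3, 42.8 ± 9.61% of control, adjusted p = 0.0516, 0.0346 after rescaling). Ncor2 in the Ncor2 knockout was 6.02 ± 0.0811 against 12.5 ± 2.42 TPM (n = 3 and 3, 48.2 ± 0.649%, adjusted p = 0.558). Hdac3 (chromosome 18, 37935844 to 37955016) fell in its own knockout to 24.2 ± 8.19% of control (7.13 ± 2.41 against 29.4 ± 2.5 TPM, log2 change -1.94 ± 0.17, adjusted p = 0.000271, n = 4 and 4). No knockout library overlapped the controls for its target. The exact permutation p was 0.0286 for each double knockout cohort without treatment and for Hdac3, and 0.1, the smallest that 3 against 3 can give, for the single Ncor knockouts. In Hdac3 knockout livers Ncor2 rose (12.03 ± 0.757 against 8.79 ± 0.639 TPM, log2 change 0.41 ± 0.079, adjusted p = 0.00586), and Ncor1 was 23.8 ± 0.961 against 21.6 ± 2.09 TPM (adjusted p = 0.212). In day 15 double knockout livers Hdac3 rose (38.6 ± 1.13 against 29.2 ± 2.57 TPM, log2 change 0.3956 ± 0.089, adjusted p = 0.00273). TPM covers the whole gene and the other liver cell types, and the deleted exons are not given in the sources used here.

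**Figure D1:**
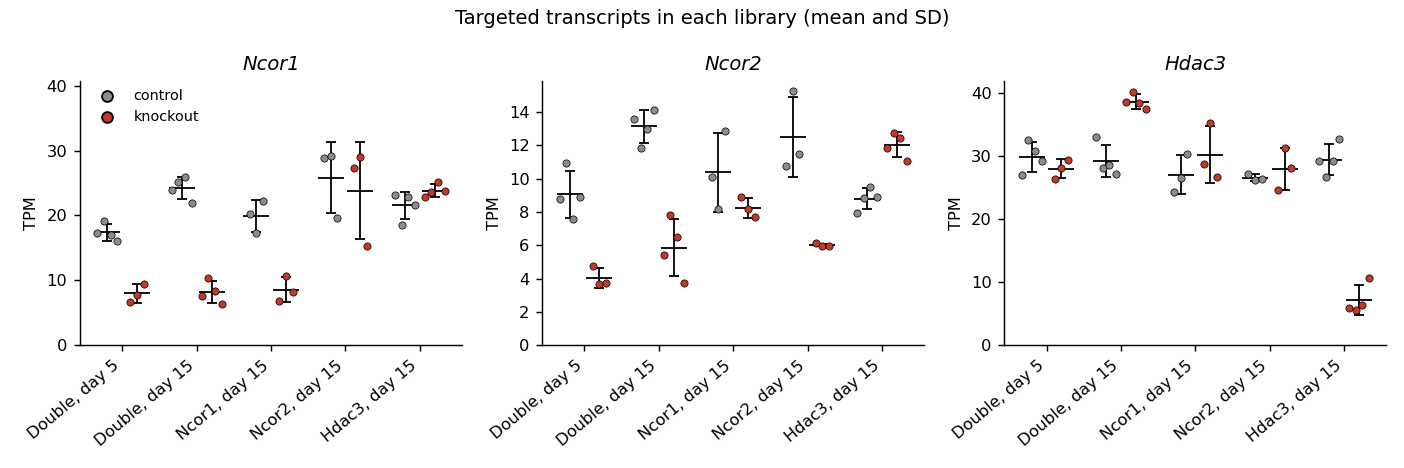
Levels of the targeted transcripts in the 5 knockout cohorts. Vertical axes give TPM of Ncor1, Ncor2 and Hdac3, and the horizontal axis gives the cohort. Each point is a library, grey for control and red for knockout, with mean ± SD (n = 3 or 4 per group). Hdac3 stood at 7.13 ± 2.41 TPM in its knockout and at 29.4 ± 2.5 TPM in the controls.

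The day 5 double knockout asked what the liver loses or gains soon after both corepressors are deleted. Pck1 (chromosome 2, 173153048 to 173159273), which encodes the cytosolic PEPCK of gluconeogenesis, fell (475 ± 340 against 1467 ± 415 TPM, log2 change -1.81 ± 0.38, adjusted p = 0.00485, n = 3 and 4, exact p = 0.0571). Fbp1 (chromosome 13, 62864753 to 62888282), the fructose-1,6-bisphosphatase of the same pathway, fell (459 ± 85.1 against 1228 ± 175 TPM, log2 change -1.42 ± 0.16, adjusted p = 0.000127). G6pc (chromosome 11, 101367561 to 101377903), which encodes the catalytic subunit of glucose-6-phosphatase, rose (307 ± 86.2 against 117 ± 79.4 TPM, log2 change 1.59 ± 0.44, adjusted p = 0.0181), a call lost when knockout library 2 was left out. Slc37a4, the glucose-6-phosphate transporter, fell (-1.66 ± 0.13 log2). Of the gluconeogenesis list, 5 of 19 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.833), and after rescaling 8 rose and 6 fell. Its median change was -0.09 and its mean -0.125, while camera ranked it upward among all genes.

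Glucocorticoid-related genes moved both ways. The glucocorticoid receptor gene Nr3c1 (chromosome 18, 39410545 to 39519421) fell (14.7 ± 1.2 against 20.02 ± 0.898 TPM, log2 change -0.42 ± 0.104, adjusted p = 0.0107). Hsd11b1 (chromosome 1, 193221634 to 193264075), whose enzyme regenerates active glucocorticoid, fell (261 ± 63.5 against 728 ± 33.6 TPM, log2 change -1.499 ± 0.15, adjusted p = 7.27e-05). The receptor targets Tat, a tyrosine aminotransferase (-0.79 ± 0.17 log2), Tsc22d3 (-1.86 ± 0.29) and Per1 (-1.69 ± 0.17) fell. Fkbp5 was 27.8 ± 2.99 against 23.1 ± 7.01 TPM (adjusted p = 0.311). Pdk4, a pyruvate dehydrogenase kinase that is also a PPARα target, rose (444 ± 32.7 against 3.13 ± 1.94 TPM, log2 change 6.89 ± 0.34, adjusted p = 2.01e-06), as did Gadd45b (4.94 ± 0.25). Of the glucocorticoid list, 5 of 29 rose and 9 fell (the same adjusted over the list alone, camera adjusted p = 0.454). Its median was -0.067 and its mean 0.229, with an upward camera direction. Of the clock genes, 3 of 18 rose and 10 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.108). Arntl, the core clock activator, rose (4.797 ± 0.479 against 0.485 ± 0.192 TPM, log2 change 1.97 ± 0.15, adjusted p = 1.85e-05) and Rorc fell (-2.41 ± 0.13).

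Lipid genes moved strongly at day 5. Of the targets of PPARα, the receptor that drives fatty acid oxidation, 25 of 30 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 2.92e-19, adjusted p = 0.0817 with an estimated correlation). Fgf21, a fasting hormone of the liver, rose (102 ± 64.2 against 0.867 ± 0.701 TPM, log2 change 5.54 ± 0.51, adjusted p = 4.76e-05). Among lipid droplet genes 10 of 15 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 6.86e-06, adjusted p = 0.168 with an estimated correlation). They included Cidec, a droplet fusion protein (55.98 ± 23 against 3.42 ± 0.465 TPM, log2 change 3.596 ± 0.26, adjusted p = 1.43e-05), and Plin2, a droplet coat protein (3.02 ± 0.15 log2). Among lipogenesis genes 11 of 23 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.671 with an estimated correlation). Scd1 (chromosome 19, 44394455 to 44407879), the stearoyl-CoA desaturase, rose (12510 ± 2130 against 1498 ± 594 TPM, log2 change 3.12 ± 0.25, adjusted p = 2.55e-05) and Pklr, the liver pyruvate kinase, fell (-2.67 ± 0.202). Cholesterol synthesis moved down: 23 of 24 fell and 0 rose (24 and 0 adjusted over the list alone, camera adjusted p = 3.52e-10, adjusted p = 0.453 with an estimated correlation). Msmo1 (-2.42 ± 0.25) and Idi1 (-2.04 ± 0.24) were examples.

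Most genes of defence against oxidants and foreign compounds rose at day 5. Of the NRF2 targets, 22 of 23 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 4.82e-19, adjusted p = 0.132 with an estimated correlation). Cbr3, a carbonyl reductase, rose (119 ± 67 against 0.853 ± 0.579 TPM, log2 change 5.86 ± 0.404, adjusted p = 1.12e-05), as did Abcc4, an efflux pump (4.99 ± 0.19 log2). Of the CAR and PXR targets, 15 of 21 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 2.59e-08, adjusted p = 0.132 with an estimated correlation). Among male-biased genes 16 of 23 fell and 0 rose (19 and 1 adjusted over the list alone, camera adjusted p = 0.000331, adjusted p = 0.721 with an estimated correlation), and among female-biased genes 9 of 16 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 2.47e-05, adjusted p = 0.132 with an estimated correlation). Hsd3b5, a male-biased steroid enzyme, fell (6.42 ± 11.1 against 219 ± 96.4 TPM, log2 change -6.16 ± 0.92, adjusted p = 0.000671). The female-biased Cyp2a4, whose reads may be shared with its close copy Cyp2a5, rose (5.99 ± 0.66). Among amino acid catabolism genes 18 of 30 fell and 2 rose (19 and 3 adjusted over the list alone, camera adjusted p = 0.0093, adjusted p = 0.721 with an estimated correlation), and 14 fell and 4 rose after rescaling. C9, a terminal complement component, fell (-4.19 ± 0.53), and so did Cyp8b1, the sterol 12α-hydroxylase (-3.56 ± 0.65).

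Among proliferation genes 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.000122, adjusted p = 0.671 with an estimated correlation), and among fibrosis genes 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.000248, adjusted p = 0.671 with an estimated correlation). The cell cycle gene Ube2c (1.43 ± 0.36 log2) and the basement membrane collagen Col4a1 (1.88 ± 0.22) rose. Immediate early genes followed: 7 of 19 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.671 with an estimated correlation), or 11 and 2 after rescaling. Of the endothelial markers, 5 of 20 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.0351, adjusted p = 0.734 with an estimated correlation), or 8 and 1 after rescaling. The markers of Kupffer cells, the resident liver macrophages, gave 0 of 20 called (0 adjusted over the list alone, camera adjusted p = 0.535). In total 4116 of 11000 tested genes changed, 1320 up (367 over 2-fold) and 2796 down (619). The median of all genes was -0.128, and rescaling by median ratios moved it to -0.006 and the split to 2093 up and 2027 down.

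At day 15 the double knockout asked what a longer loss does. Pck1 fell (124 ± 37.2 against 1515 ± 748 TPM, log2 change -3.45 ± 0.396, adjusted p = 2.55e-05, n = 4 and 4), and Fbp1 fell (128 ± 12.5 against 1074 ± 59.8 TPM, log2 change -3.06 ± 0.0902, adjusted p = 7.24e-10). Slc37a4 fell (-2.97 ± 0.101 log2), as did Sds, a serine dehydratase that feeds gluconeogenesis (-1.82 ± 0.18). G6pc was 133 ± 48.4 against 188 ± 84.7 TPM (adjusted p = 0.26, exact p = 0.314). Of the gluconeogenesis list, 11 of 19 fell and 5 rose (the same adjusted over the list alone, camera adjusted p = 0.123). Fry asks whether a list's genes move, on balance, in one direction, its mixed form whether they move in either, and neither compares them with other genes. Fry gave adjusted p = 0.000137 for gluconeogenesis at day 15, 0.0524 at day 5 and 0.00704 in the vehicle-treated double knockout. For the same list it gave 0.0325 in the Hdac3 knockout, where the mean change was 0.124 log2. In the Ncor1 and Ncor2 knockouts fry gave 0.931 and 0.869. Hsd11b1 fell (22.4 ± 4.08 against 789 ± 75.5 TPM, log2 change -5.08 ± 0.12, adjusted p = 1.81e-10), and so did Nr3c1 (11.5 ± 1.14 against 24.2 ± 2.1 TPM, log2 change -1.01 ± 0.11, adjusted p = 1.34e-05) and Tat (79.8 ± 30 against 856 ± 661 TPM, log2 change -3.21 ± 0.44, adjusted p = 9.28e-05). Fkbp5 was 25.9 ± 3.13 against 34.2 ± 12.7 TPM (adjusted p = 0.248). Of the glucocorticoid list, 12 of 30 rose and 11 fell (the same adjusted over the list alone, camera adjusted p = 0.877), with median -0.02, mean 0.251 and an upward camera direction.

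**Figure D2:**
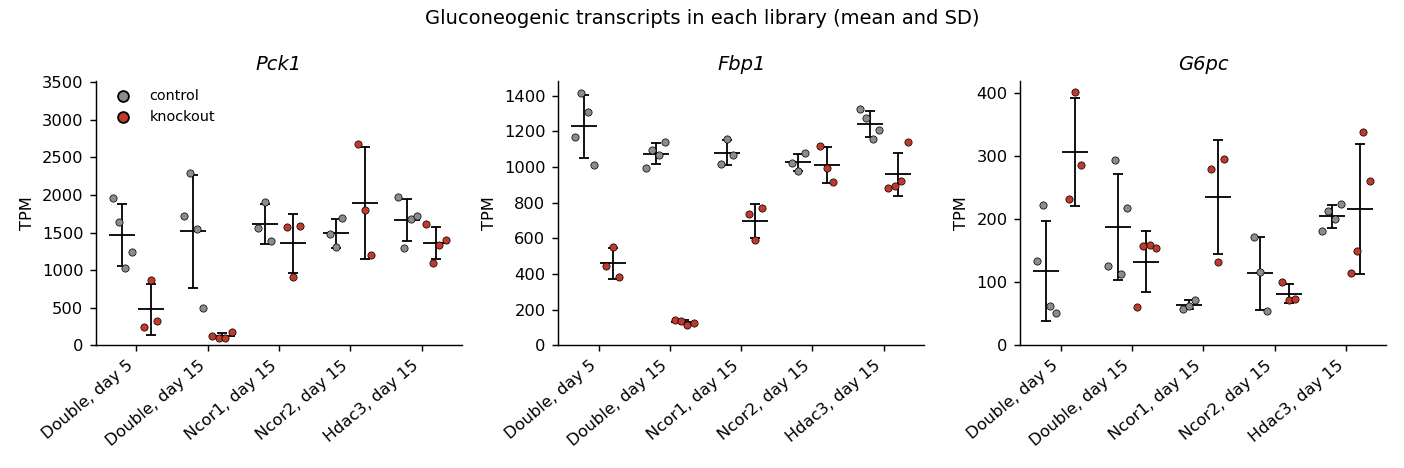
Gluconeogenic transcripts in the 5 knockout cohorts. Vertical axes give TPM of Pck1, Fbp1 and G6pc, and the horizontal axis gives the cohort. Grey points are control and red points knockout libraries, with mean ± SD (n = 3 or 4 per group). Fbp1 stood at 128 ± 12.5 TPM in day 15 double knockout livers and at 1074 ± 59.8 TPM in their controls.

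Most genes of the hepatocyte functions listed here fell at day 15. Of the hepatocyte identity genes, 19 of 23 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 1.84e-05, adjusted p = 0.23 with an estimated correlation). Of the amino acid catabolism genes, 24 of 30 fell and 3 rose (the same adjusted over the list alone, camera adjusted p = 9.32e-07, adjusted p = 0.351 with an estimated correlation). Prodh2, a hydroxyproline dehydrogenase, fell (1.03 ± 0.51 against 189 ± 2.35 TPM, log2 change -6.58 ± 0.17, adjusted p = 2.17e-10), as did Otc of the urea cycle (-3.94 ± 0.21 log2). For bile acid synthesis and transport, 15 of 22 fell and 5 rose (16 and 5 adjusted over the list alone, camera adjusted p = 0.00494, adjusted p = 0.351 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (-2.41 ± 0.31), and so did Slc10a1, the main bile salt importer (-5.802 ± 0.27). For pericentral genes, 15 of 19 fell and 3 rose (the same adjusted over the list alone, camera adjusted p = 0.00239, adjusted p = 0.47 with an estimated correlation). Cyp2e1, a pericentral cytochrome P450, fell (590.2 ± 56 against 11070 ± 782 TPM, log2 change -4.23 ± 0.093, adjusted p = 1.03e-10). For male-biased genes, 20 of 23 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.391 with an estimated correlation), and for acute phase genes, 17 of 29 fell and 7 rose (the same adjusted over the list alone, camera adjusted p = 0.0244, adjusted p = 0.391 with an estimated correlation). Car3, a carbonic anhydrase, fell (2.85 ± 3.95 against 2764 ± 435 TPM, log2 change -9.92 ± 0.47, adjusted p = 2.14e-08), as did C8b, a terminal complement component (-7.63 ± 0.18). Mup3, of a multicopy family whose copies may share reads, fell (-8.74 ± 0.35). For clock genes, 12 of 19 fell and 4 rose (13 and 4 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.491 with an estimated correlation). Dbp fell (-3.14 ± 0.16) and Arntl rose (6.12 ± 1.11 against 0.324 ± 0.112 TPM, log2 change 2.42 ± 0.15, adjusted p = 1.53e-07).

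Most NRF2, p53 and PPARα targets rose at day 15, and ER stress (8 up, 9 down of 24) and lipogenesis genes moved both ways. For the NRF2 targets, 23 of 24 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 4.54e-12, adjusted p = 0.113 with an estimated correlation), and for the PPARα targets, 24 of 30 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 9.32e-07, adjusted p = 0.391 with an estimated correlation). Cbr3 rose (447 ± 36.1 against 1.22 ± 0.721 TPM, log2 change 7.71 ± 0.196, adjusted p = 2.32e-10), as did Ehhadh, a peroxisomal oxidation enzyme (9246 ± 861 against 238 ± 24.8 TPM, log2 change 5.27 ± 0.102, adjusted p = 5.94e-11). For p53 targets, 15 of 20 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 7.64e-05, adjusted p = 0.113 with an estimated correlation), and for immediate early genes, 16 of 22 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.000194, adjusted p = 0.351 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose (122 ± 13.6 against 2.098 ± 0.485 TPM, log2 change 5.32 ± 0.13, adjusted p = 2.23e-10), as did the stress factor Atf3 (4.199 ± 0.16 log2). Scd1 rose (9850 ± 1550 against 617 ± 268 TPM, log2 change 4.1 ± 0.29, adjusted p = 5.77e-07), and Cidec (chromosome 6, 113424634 to 113435760) rose (118 ± 25.1 against 2.45 ± 0.263 TPM, log2 change 5.09 ± 0.14, adjusted p = 5.8e-10). Over lipogenesis 10 of 23 fell and 6 rose (the same adjusted over the list alone, camera adjusted p = 0.539). Sult2a1 and Sult2a2, near copies, were at 0 in all 4 controls and at 54.9 to 509.5 (Sult2a1) and 115 to 748 TPM (Sult2a2) in knockouts. Sprr1a, a cornified envelope gene, was at 0 in controls and 177 to 382 TPM in knockouts.

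Most markers of the other liver cell types listed here rose in the same livers. Of the Kupffer cell and macrophage markers, 23 of 25 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 4.64e-07, adjusted p = 0.351 with an estimated correlation). Trem2, a receptor of lipid-associated macrophages, rose (32.1 ± 26.6 against 0.413 ± 0.377 TPM, log2 change 4.03 ± 0.64, adjusted p = 0.000284). For fibrosis and stellate cell genes, 20 of 25 rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 1.45e-07, adjusted p = 0.351 with an estimated correlation). The fibrillar collagen Col1a1 rose (51.6 ± 10.1 against 2.87 ± 0.946 TPM, log2 change 3.77 ± 0.18, adjusted p = 2.16e-08). For proliferation, 24 of 27 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 9.32e-07, adjusted p = 0.396 with an estimated correlation), and for inflammation, 12 of 17 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00649, adjusted p = 0.44 with an estimated correlation). For endothelial markers, 15 of 20 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.541 with an estimated correlation), and for cholangiocyte markers, 10 of 15 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.47 with an estimated correlation). For T and NK cells, 7 of 9 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.0211, adjusted p = 0.396 with an estimated correlation), and for B cells, 5 of 5 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.0345, adjusted p = 0.351 with an estimated correlation). Ube2c (2.39 ± 0.34 log2), the monocyte attractant Ccl2 (2.66 ± 0.196) and Lyve1 of sinusoidal endothelium (2.37 ± 0.19) were among the raised genes. In total 7304 of 11770 genes changed, 3619 up (1352 over 2-fold) and 3685 down (1189).

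Whether the double knockout effect itself differed between the days was tested as a difference of effects. The falls were larger at day 15 for Fbp1 (log2 difference -1.64 ± 0.18, adjusted p = 7.36e-06), Hsd11b1 (-3.59 ± 0.199, adjusted p = 8.52e-09), Tat (-2.42 ± 0.55, adjusted p = 0.00378) and Nr3c1 (-0.59 ± 0.14, adjusted p = 0.00464). For Pck1 the difference was -1.64 ± 0.63, adjusted p = 0.0607. G6pc had a lower effect at day 15 (-2.08 ± 0.64, adjusted p = 0.0227), a call lost without day 5 knockout library 2. Fgf21 did too (-3.56 ± 1.06, adjusted p = 0.019), a call lost without day 5 knockout library 3. Effects were higher at day 15 for 21 of 25 Kupffer markers and lower for 0 (the same adjusted over the list alone, camera adjusted p = 1.94e-07, adjusted p = 0.363 with an estimated correlation). Trem2 stood at 4.11 ± 0.81 log2. For hepatocyte genes effects were lower for 11 of 23 and higher for 2 (12 and 2 adjusted over the list alone, camera adjusted p = 3.36e-06, adjusted p = 0.0952 with an estimated correlation), and for gluconeogenesis for 9 of 19 and higher for 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.363 with an estimated correlation). For cholesterol synthesis they were higher for 13 of 24 and lower for 2 (16 and 3 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.61 with an estimated correlation). Sqle, the squalene epoxidase, stood at 2.24 ± 0.45. The effect differed for 3309 of 11500 genes, higher at day 15 for 2013 and lower for 1296 (1928 and 1907 after rescaling). The days were separate cohorts, each set against its own controls.

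The Ncor1 knockout asked what the loss of this corepressor alone does at day 15. Cyp4a10, a fatty acid hydroxylase, rose (2426 ± 793 against 358 ± 140 TPM, log2 change 2.79 ± 0.35, adjusted p = 0.0141, n = 3 and 3), and Ehhadh rose (1185 ± 561 against 160.4 ± 11.3 TPM, log2 change 2.78 ± 0.29, adjusted p = 0.0122). Both are PPARα targets, of which 7 of 29 rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 5.1e-13, adjusted p = 0.336 with an estimated correlation), with 2 and 0 after rescaling. Acacb, the mitochondrial acetyl-CoA carboxylase, rose (31.7 ± 6.81 against 7.74 ± 1.84 TPM, log2 change 1.9 ± 0.22, adjusted p = 0.0122), as did Scd1 (2.08 ± 0.28 log2, adjusted p = 0.0613 after rescaling). Over lipogenesis 3 of 23 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00271, adjusted p = 0.514 with an estimated correlation). Of the CAR and PXR targets, 7 of 21 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.05e-09, adjusted p = 0.0763 with an estimated correlation), with 2 and 0 after rescaling. G6pc rose (235 ± 90 against 64.1 ± 7.01 TPM, log2 change 1.78 ± 0.29, adjusted p = 0.0401, adjusted p = 0.0847 after rescaling). Pck1 was 1354 ± 387 against 1614 ± 266 TPM (adjusted p = 0.545) and Fbp1 697 ± 95.7 against 1080 ± 72 TPM (adjusted p = 0.13). Col27a1, a fibrillar collagen, fell (0.609 ± 0.192 against 11.03 ± 2.72 TPM, log2 change -2.88 ± 0.23, adjusted p = 0.00319). Among gluconeogenesis genes 1 of 20 rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.689), 0 and 0 after rescaling, with median -0.049, mean 0.023 and a downward camera direction. Among glucocorticoid genes 1 of 30 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.187), 0 and 0 after rescaling, and Nr3c1 was 32.7 ± 8.6 against 22.4 ± 1.24 TPM (adjusted p = 0.279).

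Erythroid, Kupffer and hepatocyte lists ranked low in Ncor1 knockout livers without a called member, and fibrosis, T and NK cell, endothelial and cholangiocyte lists did not pass (camera adjusted p from 0.119 to 0.684). For the hepatocyte list of 23 genes the camera adjusted p was 0.0324 (0.336 with an estimated correlation). Among erythroid markers 0 of 6 rose and 0 fell (0 and 4 adjusted over the list alone, camera adjusted p = 2.06e-06, adjusted p = 0.336 with an estimated correlation). Hba-a1, an α-globin, was 1160 ± 403 against 3495 ± 1540 TPM (adjusted p = 0.102). Among Kupffer markers 0 of 19 rose and 0 fell (0 and 5 adjusted over the list alone, camera adjusted p = 1.73e-05, adjusted p = 0.396 with an estimated correlation). C1qa was 38.4 ± 6.48 against 80.2 ± 15.2 TPM (adjusted p = 0.0729). In total 55 of 10917 genes changed, 48 up and 7 down. Col27a1 was among those called, yet the count depended on single libraries: 3 without control 2, 12 without control 1, 22 without control 3 and 19 without knockout 3. It was 23 after rescaling, 0 with no filter on low values (1990 at unadjusted p under 0.05, limma) and 1617 with all 47 libraries in the fit. Of the genes named here, Col27a1 alone was called whichever library was left out, and the calls of Cyp4a10, Ehhadh, Acacb, Scd1 and G6pc were all lost without control 2.

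The Ncor2 knockout asked the same of Ncor2. Orm2 (chromosome 4, 63362449 to 63365878), an acute phase glycoprotein gene, rose (86.8 ± 7.56 against 19.4 ± 3.39 TPM, log2 change 2.11 ± 0.17, adjusted p = 0.00654, n = 3 and 3). It was the 1 gene of 11117 to change (419 at unadjusted p under 0.05). Its call was lost without knockout library 1 or 2, where the count was 0 (259 and 436 at unadjusted p under 0.05, limma). Without knockout library 3 the count was 5, and with all libraries in the fit it was 3. Pck1 was 1894 ± 747 against 1490 ± 196 TPM, G6pc 82.04 ± 15.4 against 114 ± 58.5 TPM and Fbp1 1009 ± 101 against 1026 ± 49.3 TPM (adjusted p = 0.996, 0.996 and 0.998). Among gluconeogenesis genes 0 of 20 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.548). Male-biased genes ranked low: 0 of 24 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 6.56e-12, adjusted p = 0.386 with an estimated correlation). Mup3, of a multicopy family, was 9244 ± 902 against 14600 ± 6440 TPM (adjusted p = 0.996). Acute phase genes ranked high: 1 of 29 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.35e-07, adjusted p = 0.386 with an estimated correlation). Kupffer markers ranked high: 0 of 20 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 6.56e-12, adjusted p = 0.49 with an estimated correlation). Other lists that ranked high with 0 called were the female-biased (camera adjusted p = 1.13e-07), NRF2 (1.6e-05), cholesterol (2.17e-05), CAR and PXR (9.84e-05) and erythroid ones (0.000269, median 1.401 log2). So did the periportal (0.00194), neutrophil (0.0138), interferon (0.0219) and endothelial lists (0.043). The thyroid (0.0128), hepatocyte (0.0128), lipogenesis (0.0219) and glycogen and glycolysis lists (0.0219) ranked low. With an estimated correlation the adjusted p of these 13 was 0.386 to 0.807.

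The Hdac3 knockout asked what the enzyme of the complex contributes at day 15. Cfd, which encodes adipsin, rose (96.7 ± 48.7 against 0.636 ± 0.275 TPM, log2 change 5.78 ± 0.31, adjusted p = 4.91e-05, n = 4 and 4), and so did Cidec (68.7 ± 33.4 against 3.62 ± 1.35 TPM, log2 change 3.77 ± 0.402, adjusted p = 0.00046). Scd1 rose (8613 ± 2730 against 1783 ± 737 TPM, log2 change 2.31 ± 0.32, adjusted p = 0.00151), and Fasn, the fatty acid synthase, rose (295 ± 50.6 against 68.1 ± 18.1 TPM, log2 change 2.12 ± 0.199, adjusted p = 0.000321). Of the lipogenesis genes, 16 of 23 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 9.53e-14, adjusted p = 0.227 with an estimated correlation). Of the PPARα targets, 22 of 29 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 3.2e-15, adjusted p = 0.252 with an estimated correlation). Among lipid droplet genes 11 of 15 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 7.04e-08, adjusted p = 0.227 with an estimated correlation). Cyp4a14 (3.76 ± 0.78 log2) and Plin2 (1.39 ± 0.23) were examples. Of the NRF2 targets, 15 of 23 rose and 1 fell (18 and 2 adjusted over the list alone, camera adjusted p = 7.8e-09, adjusted p = 0.252 with an estimated correlation). Among male-biased genes 15 of 24 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 1.43e-05, adjusted p = 0.252 with an estimated correlation), and among female-biased genes 7 of 14 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 2.49e-05, adjusted p = 0.252 with an estimated correlation). Hsd3b5 fell (3.91 ± 3.24 against 213 ± 8.77 TPM, log2 change -5.67 ± 0.36, adjusted p = 6.04e-05). Of the interferon-stimulated genes, 13 of 24 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 0.000264, adjusted p = 0.475 with an estimated correlation). Irf7 was an example (20.8 ± 1.24 against 75.9 ± 26.5 TPM, log2 change -1.75 ± 0.21, adjusted p = 0.000643).

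Of the gluconeogenesis genes in Hdac3 knockout livers, 5 of 20 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.0569), and 5 rose and 0 fell after rescaling. Gpd1, a glycerol-3-phosphate dehydrogenase, rose (537 ± 90.5 against 182 ± 5.67 TPM, log2 change 1.54 ± 0.12, adjusted p = 0.00015), as did Pcx, the pyruvate carboxylase (316 ± 16.5 against 211 ± 9.55 TPM, log2 change 0.58 ± 0.064, adjusted p = 0.000536). Fbp1 fell (958 ± 123 against 1240 ± 73.7 TPM, log2 change -0.38 ± 0.097, adjusted p = 0.0194, adjusted p = 0.0504 after rescaling), a call also lost without knockout library 1, 2 or 3. Pck1 was 1362 ± 217 against 1670 ± 282 TPM (adjusted p = 0.173) and G6pc 216 ± 103 against 205 ± 18.3 TPM (adjusted p = 0.914). Nr3c1 was 25.8 ± 2.29 against 29.02 ± 1.6 TPM (adjusted p = 0.142). Of the glucocorticoid genes, 6 of 29 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.305 with an estimated correlation). Cyp7a1 rose (189 ± 60.7 against 92.1 ± 16.4 TPM, log2 change 0.98 ± 0.23, adjusted p = 0.013). Among clock genes 6 of 17 fell and 2 rose (7 and 4 adjusted over the list alone, camera adjusted p = 0.925), or 3 and 4 after rescaling. Endothelial markers (11 up and 0 down of 20, 13 and 0 adjusted over the list alone, camera adjusted p = 4.86e-08, adjusted p = 0.275 with an estimated correlation) and fibrosis genes (8 up and 0 down of 22, 11 and 0 adjusted over the list alone, camera adjusted p = 7.87e-07, adjusted p = 0.252 with an estimated correlation) ranked high. Of the Kupffer markers 0 of 20 were called (0 adjusted over the list alone, camera adjusted p = 0.0252, adjusted p = 0.618 with an estimated correlation). In total 2881 of 11104 genes changed, 1109 up (148 over 2-fold) and 1772 down (117), or 1450 up and 1161 down after rescaling. Without knockout library 2 the count was 1864 and without library 3 it was 1801, and with all libraries in the fit it was 1612.

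How the day 15 effects of the double and the Hdac3 knockout differed was tested directly. The double knockout effect was lower for Pck1 (log2 difference -3.16 ± 0.48, adjusted p = 5.09e-05), Fbp1 (-2.68 ± 0.13, adjusted p = 1.24e-10), Hsd11b1 (-4.599 ± 0.18, adjusted p = 1.48e-11), Tat (-3.71 ± 0.53, adjusted p = 2.69e-05) and Nr3c1 (-0.85 ± 0.13, adjusted p = 4.13e-05). For G6pc the difference was -0.44 ± 0.51, adjusted p = 0.514. It was lower for 11 of 20 gluconeogenesis genes and higher for 4 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00524, adjusted p = 0.296 with an estimated correlation). Among amino acid catabolism genes it was lower for 23 of 30 and higher for 1 (26 and 1 adjusted over the list alone, camera adjusted p = 5.56e-10, adjusted p = 0.217 with an estimated correlation). Prodh2 stood at -4.91 ± 0.33 log2. Among lipogenesis genes it was lower for 15 of 23 and higher for 1 (16 and 1 adjusted over the list alone, camera adjusted p = 6.99e-05, adjusted p = 0.382 with an estimated correlation). Pklr stood at -3.66 ± 0.299, Thrsp at -2.68 ± 0.47 and, the other way, Scd1 at 1.79 ± 0.48. Among interferon-stimulated genes it was higher for 15 of 25 and lower for 1 (16 and 1 adjusted over the list alone, camera adjusted p = 0.000633, adjusted p = 0.491 with an estimated correlation), and among Kupffer markers for 20 of 25 and lower for 0 (21 and 0 adjusted over the list alone, camera adjusted p = 2.17e-05, adjusted p = 0.316 with an estimated correlation). Irf7 stood at 1.82 ± 0.34 and Trem2 at 3.84 ± 0.77. In total the effects differed for 5248 of 11537 genes, higher in the double knockout for 2755 and lower for 2493.

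**Figure D3:**
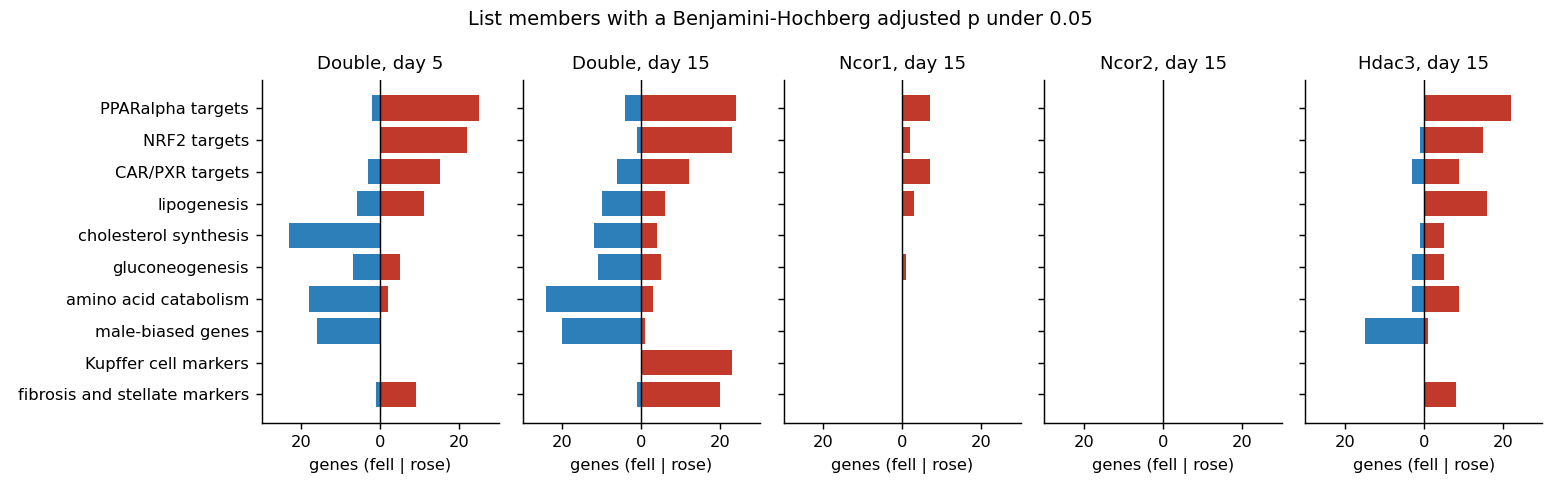
Called members of 10 gene lists in the 5 knockout comparisons. The horizontal axis gives the number of genes, those that rose in red to the right and those that fell in blue to the left, and each bar is a list. Groups are the double knockout at day 5 and day 15 and the Ncor1, Ncor2 and Hdac3 knockouts (n = 3 or 4 libraries per group). Of 30 PPARα targets, 25 rose at day 5 in the double knockout.

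The vehicle-treated livers of the dexamethasone experiment gave the day 5 double knockout in other libraries, from mice injected 2 h before death (n = 3 and 3). Pck1 fell (662 ± 240 against 2080 ± 216 TPM, log2 change -1.71 ± 0.21, adjusted p = 4.12e-05), and Fbp1 fell (279 ± 58 against 1369 ± 75.3 TPM, log2 change -2.31 ± 0.16, adjusted p = 3.31e-07). G6pc rose (256 ± 54.4 against 124 ± 57.3 TPM, log2 change 1.14 ± 0.36, adjusted p = 0.021), a call lost without control 1 (0.7079 log2) or knockout 2 or 3. Among gluconeogenesis genes 9 of 20 fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 0.279). Fkbp5 (chromosome 17, 28399094 to 28517527), a chaperone and glucocorticoid receptor target, fell (28.6 ± 4.92 against 101 ± 28.8 TPM, log2 change -1.75 ± 0.18, adjusted p = 9.64e-06), and Tsc22d3 fell (26.1 ± 3.37 against 100.1 ± 11.2 TPM, log2 change -1.897 ± 0.17, adjusted p = 2e-06). In the untreated day 5 cohort Fkbp5 was 27.83 ± 2.99 against 23.15 ± 7.01 TPM (adjusted p = 0.311). Its level thus differed between the control groups of these experiments, while the knockout levels were close. Hsd11b1 (-2.04 ± 0.15 log2), Nr3c1 (-0.81 ± 0.24) and the coactivator gene Ppargc1a (-1.25 ± 0.196) fell, and Gadd45b rose (3.87 ± 0.23). Nr3c1 was at 6.144 TPM in knockout library 1 and at 15.33 and 14.06 TPM in the others, and without library 1 its change was -0.4349 log2 (adjusted p = 0.00622). Among glucocorticoid genes 14 of 30 fell and 7 rose (the same adjusted over the list alone, camera adjusted p = 0.61). Of the NRF2 targets, 21 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 3.92e-20, adjusted p = 0.0793 with an estimated correlation). Of the PPARα targets, 23 of 30 rose and 3 fell (24 and 3 adjusted over the list alone, camera adjusted p = 8.36e-13, adjusted p = 0.381 with an estimated correlation).

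Hsd3b5 was listed at 0 in all 3 vehicle-treated knockouts and at 21.1, 32.9 and 1.33 TPM in their controls. Among endothelial markers 16 of 19 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 5.53e-09, adjusted p = 0.381 with an estimated correlation). Among Kupffer markers 3 of 18 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.598 with an estimated correlation), or 8 and 1 after rescaling. In total 4933 of 10713 genes changed, 1624 up and 3309 down. The median of all genes was -0.201, and after rescaling -0.016, with 2503 up and 2439 down.

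Dexamethasone in control livers asked which genes respond to glucocorticoid within 2 h. Tat (chromosome 8, 109990437 to 109999803) rose (3959 ± 191 against 1295 ± 75.4 TPM, log2 change 1.61 ± 0.17, adjusted p = 8.88e-05, n = 3 and 3), as did Fkbp5 (246 ± 15.2 against 101 ± 28.8 TPM, log2 change 1.32 ± 0.18, adjusted p = 0.000776). The kinase gene Sgk1 (chromosome 10, 21882184 to 21999903) rose (94.8 ± 25.3 against 9.79 ± 1.42 TPM, log2 change 3.13 ± 0.19, adjusted p = 1.12e-06). Gadd45b (chromosome 10, 80930073 to 80932204), a stress gene, rose (87.3 ± 23.6 against 4.49 ± 1.64 TPM, log2 change 4.03 ± 0.23, adjusted p = 1.12e-06). Of the glucocorticoid list, 18 of 30 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 4.14e-27, adjusted p = 0.0222 with an estimated correlation). Pck1 was 3189 ± 319 against 2080 ± 216 TPM (log2 change 0.62 ± 0.21, adjusted p = 0.108, 0.0275 after rescaling, exact p = 0.1). Sds rose (1155 ± 102 against 580.2 ± 90.8 TPM, log2 change 1.001 ± 0.17, adjusted p = 0.00287). G6pc fell (45.4 ± 21.5 against 124 ± 57.3 TPM, log2 change -1.401 ± 0.36, adjusted p = 0.0315), a call lost without control vehicle library 2 or 3 or control dexamethasone library 1 or 3. Fbp1 was 1150 ± 135 against 1369 ± 75.3 TPM (adjusted p = 0.411). Of the gluconeogenesis genes, 2 of 20 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.176), or 6 and 1 after rescaling, with median -0.061, mean 0.056 and an upward camera direction. Nr1d1 (chromosome 11, 98767932 to 98775333), a clock repressor, fell (5.85 ± 0.872 against 28.01 ± 7.14 TPM, log2 change -2.06 ± 0.19, adjusted p = 4.67e-05), Dbp fell (-1.47 ± 0.102 log2) and Nfil3 rose (1.18 ± 0.199). Of 17 clock genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone), a list that camera did not call.

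Other genes raised by dexamethasone in controls were Ppp1r3c, which targets glycogen synthesis (172 ± 12.7 against 26.8 ± 12 TPM, log2 change 2.75 ± 0.305, adjusted p = 0.000151), and Lpin1, a phosphatidate phosphatase (2.14 ± 0.303 log2). Id2, a transcriptional inhibitor, fell (14.04 ± 1.41 against 103 ± 32.6 TPM, log2 change -2.74 ± 0.23, adjusted p = 1.47e-05). Endothelial markers ranked high: 3 of 19 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.2e-10, adjusted p = 0.487 with an estimated correlation), or 6 and 0 after rescaling. Lyve1 rose (10.9 ± 0.868 against 2.33 ± 1.45 TPM, log2 change 1.94 ± 0.305, adjusted p = 0.00177). Among Kupffer markers 0 of 18 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 4.31e-09, adjusted p = 0.518 with an estimated correlation), or 3 and 0 after rescaling. Immediate early genes ranked high too: 6 of 19 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00451, adjusted p = 0.487 with an estimated correlation). In total 824 of 10713 genes changed, 334 up (154 over 2-fold) and 490 down (125), or 562 up and 410 down after rescaling. The 4 groups shared a fit. The count was 479 without control vehicle library 1, 485 without control vehicle library 2, 547 without control dexamethasone library 1, 458 without control dexamethasone library 3 and 1542 without knockout vehicle library 1.

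In double knockout livers the same dose asked whether glucocorticoid still acts. Tat rose (2673 ± 171 against 859 ± 227 TPM, log2 change 1.67 ± 0.17, adjusted p = 0.000176, n = 3 and 3), and so did Fkbp5 (105 ± 3.21 against 28.6 ± 4.92 TPM, log2 change 1.86 ± 0.18, adjusted p = 0.000176) and Tsc22d3 (62.5 ± 4.92 against 26.1 ± 3.37 TPM, log2 change 1.23 ± 0.17, adjusted p = 0.00196). Ddit4, an mTOR inhibitor, rose (143 ± 22.4 against 18.4 ± 2.17 TPM, log2 change 2.88 ± 0.23, adjusted p = 4.95e-05), as did Lpin1 (286 ± 40.7 against 23.5 ± 8.39 TPM, log2 change 3.603 ± 0.303, adjusted p = 6.94e-05). Of the glucocorticoid list, 13 of 30 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 5.36e-25, adjusted p = 0.0288 with an estimated correlation). Pck1 was 1098 ± 103 against 662 ± 240 TPM (log2 change 0.79 ± 0.21, adjusted p = 0.106, exact p = 0.1) and G6pc 183 ± 35.9 against 256 ± 54.4 TPM (adjusted p = 0.616). Slc37a4 rose (114 ± 10.9 against 69.2 ± 4.91 TPM, log2 change 0.703 ± 0.12, adjusted p = 0.00712). Among gluconeogenesis genes 1 of 20 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00402, adjusted p = 0.702 with an estimated correlation), or 2 and 0 after rescaling. Nr1d1 was 31.4 ± 7.52 against 44.2 ± 5.3 TPM (adjusted p = 0.322). Among clock genes 2 of 17 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.42). Inflammation genes ranked low: 3 of 14 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.00356, adjusted p = 0.33 with an estimated correlation). Il1b, an inflammatory cytokine, fell (-1.79 ± 0.25 log2). In total 184 of 10713 genes changed, 146 up (86 over 2-fold) and 38 down (14). The count was 80 without knockout dexamethasone library 1, 75 without library 2 and 112 without library 3.

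Whether the response differed between genotypes was tested as their interaction. For Pck1 the difference, double knockout minus control, was 0.18 ± 0.302, adjusted p = 0.835, and for G6pc it was 0.92 ± 0.51, adjusted p = 0.624. For Fbp1 it was 0.21 ± 0.23, adjusted p = 0.753, for Tat 0.061 ± 0.23, adjusted p = 0.929 and for Fkbp5 0.53 ± 0.26, adjusted p = 0.612. The response was smaller in double knockout livers for Gadd45b (-3.16 ± 0.33, adjusted p = 0.00226), which stood at 141 ± 18.3 against 77 ± 9.71 TPM there. It was also smaller for Sgk1 (-2.37 ± 0.26, adjusted p = 0.00268), at 28.9 ± 3.56 against 16.8 ± 2.83 TPM, and for Fam89a (-2.43 ± 0.25, adjusted p = 0.00226). Nr1d1 differed by 1.57 ± 0.28, adjusted p = 0.0514, 0.0355 after rescaling. Among glucocorticoid genes the response was lower for 3 of 30 and higher for 0 (4 and 3 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.437 with an estimated correlation). Their median was 0.04 and their mean -0.11, with a downward camera direction. Of 20 gluconeogenesis genes 0 differed (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.38). Responses of Kupffer markers ranked lower with 0 called (camera adjusted p = 8.86e-09, adjusted p = 0.36 with an estimated correlation). So did those of endothelial markers, also with 0 called (camera adjusted p = 6.48e-07, adjusted p = 0.437 with an estimated correlation).

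The interaction was called for 15 genes, 2 higher, such as Gas1, and 13 lower, such as Gadd45b. The median of all genes was 0.148, and 0 after rescaling, where 30 were called (6 higher and 24 lower). With a library left out the count was 6 (control vehicle 2), 8 and 6 (control dexamethasone 1 and 3), 23 (knockout vehicle 2), and 6, 8 and 6 (knockout dexamethasone 1, 2 and 3). With all libraries it was 25. A wider set was the 932 genes called for the mean response of both genotypes, 476 up and 456 down. Their median change in the direction of that response was 0.738 log2 in control and 0.483 in double knockout livers. The median difference was 0.269 (0.245 to 0.297, 95% bootstrap over genes). For the genes that rose the medians were 0.783 and 0.642, and for those that fell -0.699 and -0.344. With rescaled TPM these medians were 0.726 and 0.495, and -0.6 and -0.385, so how the difference divides between raised and lowered genes depends on the scaling. The difference ranged from 0.129 to 0.325 with each library left out, lowest without knockout vehicle library 2.

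**Figure D4:**
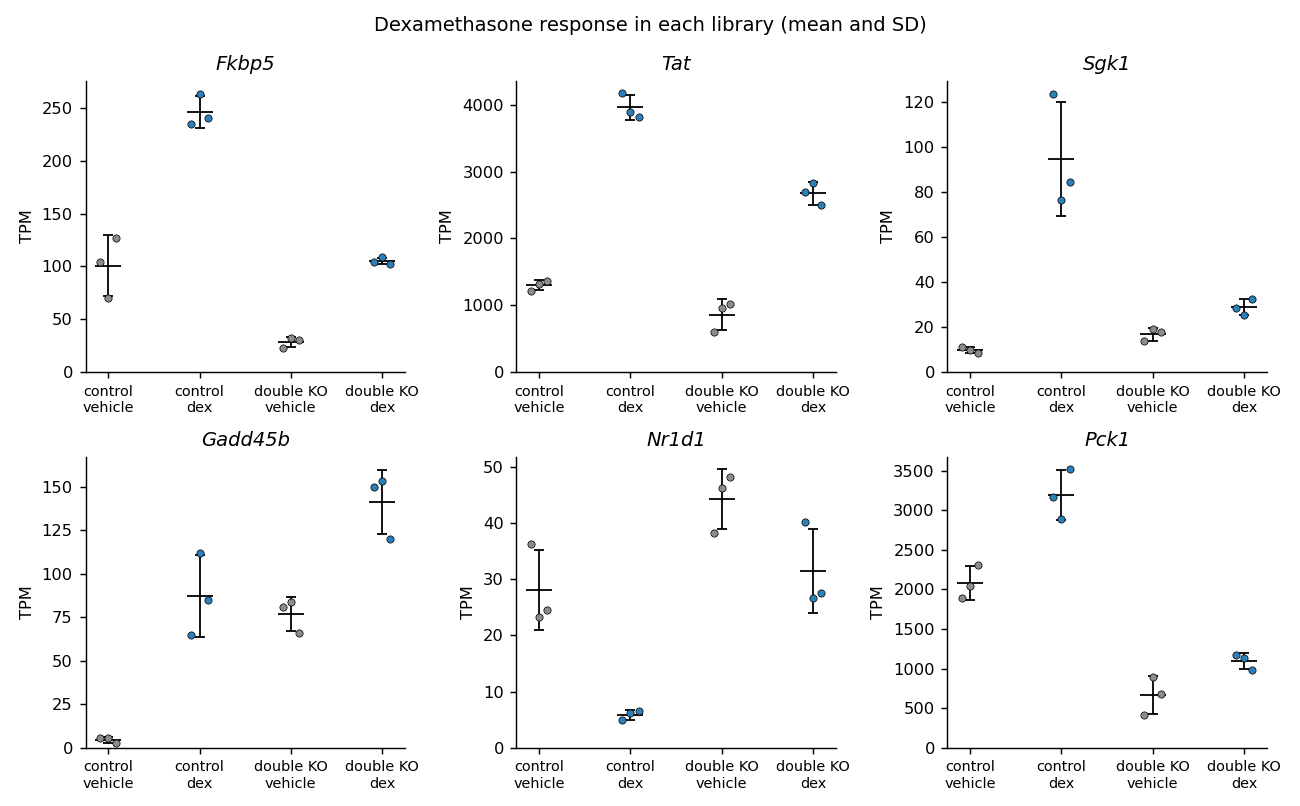
Dexamethasone-responsive transcripts in the 4 groups of the treatment experiment. Vertical axes give TPM of Fkbp5, Tat, Sgk1, Gadd45b, Nr1d1 and Pck1, and the horizontal axis gives genotype and treatment. Grey points are vehicle and blue points dexamethasone libraries, with mean ± SD (n = 3 per group). Sgk1 stood at 9.785 ± 1.42 TPM with vehicle and 94.8 ± 25.3 TPM with dexamethasone in controls, and at 16.8 ± 2.83 and 28.9 ± 3.56 TPM in double knockouts.

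Shared changes were counted between comparisons whose contrasted groups have no library in common. The dexamethasone comparisons nevertheless came from a single fit with a common spread per gene, so their values for independent lists are only a rough guide. Of the genes tested in both, the day 5 and vehicle-treated double knockouts shared 939 raised genes (197 for independent lists) and 2215 lowered genes (846), with r = 0.875. The day 15 double knockout and the Hdac3 knockout shared 647 raised (300 for independent lists) and 1153 lowered genes (584), with r = 0.507. Cidec, Scd1 and Pdk4 were among the shared raised genes. Dexamethasone raised 108 genes (4.55 for independent lists) and lowered 27 (1.74) in both genotypes, with 0 in opposite directions and r = 0.512. Tat and Fkbp5 were among the raised genes.

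The authors' deposited tables give their own tests. In the authors' deposited table for the day 15 double knockout, 4645 genes were higher and 4279 lower at adjusted p under 0.05, with Pck1 at -3.62 log2 (adjusted p = 9.72e-15). The authors' deposited table for day 5 held 2182 higher and 2033 lower, with Pck1 at -1.46 (adjusted p = 0.000697). For Hdac3, the authors' deposited table held 1023 higher and 764 lower, with Pck1 at -0.23 (adjusted p = 0.744). The authors' deposited table for the Ncor1 knockout held 799 higher and 657 lower, with Ncor1 at -1.33 (adjusted p = 8.37e-15) and Pck1 at -0.34 (adjusted p = 0.634). In the authors' deposited table for the Ncor2 knockout, 4 were higher and 7 lower, with Ncor2 at -1.04 (adjusted p = 2.97e-07) and Orm2 at 2.15 (adjusted p = 0.165). For dexamethasone, the authors' deposited table held 761 higher and 532 lower, with Pck1 at 0.73 (adjusted p = 0.00151). Its genotype is not stated, and over 10668 genes the log2 changes of the authors' deposited table correlated at r = 0.961 with those in control livers and at r = 0.488 with those in double knockout livers.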

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

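Of the tests in this part, those of the hepatocyte share and the scaling behind the cell markers, of the remaining target transcripts and of vehicle-treated double knockout library 2 were chosen after the result was seen. The test of genes not raised at day 5 was set before its own result was seen, but after the correlation beside it was known.

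The dexamethasone response over the 932 mean-response genes was smaller in double knockout than in control livers, with a median difference of 0.269 log2. Scaling between libraries did not account for it, since the difference was 0.229 (0.206 to 0.257) with rescaled TPM. The vehicle-treated double knockout library that stood apart, library 1, is not the cause either, since without it the rescaled difference was 0.262 (0.237 to 0.286). Its column name lacks the R that the others of the experiment carry, which the labels do not explain, so different handling stays open. Without it dexamethasone changed 1542 genes in controls rather than 824. The bound set in advance also asked for more than 0.1 with each other library left out. It was missed without vehicle-treated double knockout library 2 (0.0812 rescaled, 0.0552 to 0.118, and 0.129 as deposited). That difference lies above 0 over these genes, and whether library 2 carried much of the pattern stays open. Levels raised before treatment could explain part of it. Over 454 genes that rose, double knockout minus control response fell as the separate day 5 knockout effect grew (rho = -0.357, -0.443 to -0.266). The 373 of these not raised at day 5 still differed by 0.0945 (0.052 to 0.146), near the bound of 0.1, the 81 raised at day 5 by 0.367 (0.294 to 0.487), and the 141 lowered at day 5 by -0.00918 (-0.144 to 0.0618). With rescaled TPM, chosen after these were seen, the differences were 0.227 (0.196 to 0.272), 0.521 (0.437 to 0.642) and 0.109 (0.0163 to 0.206). Whether the response was smaller beyond raised levels thus depends on the scaling and stays open.

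Many markers of Kupffer and other non-hepatocyte cells rose in day 15 double knockout livers. A lower hepatocyte RNA share alone would raise other cell types alike, but the Kupffer median exceeded the endothelial by 0.984 log2 (0.623 to 1.4). It may still contribute, as endothelial markers rose. Scaling does not account for the rise (Kupffer median 1.49 rescaled). Nor does a single library (1.36 or above with any left out). Whether time or cohort made the difference from day 5 is open, as the cohorts were separate.

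The single knockouts changed far fewer genes than the double knockout at day 15. Group size does not account for this, since 16 draws of 3 against 3 libraries from the double knockout cohort called 5856 to 6858 genes. Noise that hides effects of the same size does not either: over the genes called at day 5, the larger single knockout median was 0.148 (0.127 to 0.171) of the double knockout's. Smaller effects can still be hidden by noise. Of simulated changes of 0.5 log2, 0% were called for Ncor1 and 2.99% for Ncor2, against 32.8% in the day 15 double knockout. With all libraries in a single fit, 1617 genes were called for Ncor1 and 3 for Ncor2. Less loss of the target stays open. Ncor1 stood at 42.8 ± 9.61% of control in its single knockout and at 45.9 ± 8.11% (day 5, 4116 called genes), 33.8 ± 6.95% (day 15) and 30.4 ± 14.1% (vehicle) in the double knockouts. Ncor2 stood at 48.2 ± 0.649% in its single knockout, above the double knockouts at 44.9 ± 6.65%, 44.6 ± 13.2% and 38.2 ± 12% in the same order. Both single knockouts lay within 1 SD of the day 5 double knockout, an SD that leaves out the spread of the controls.

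Other splits of the libraries asked whether chance could give the counts. It is unlikely for the day 5 double knockout (4116 genes, 1 of 35 splits as many, fewest possible, highest other 4). So it is for day 15 (7304) and Hdac3 (2881), each 1 of 35, highest other 1. For the difference between days (3309, 4 of 100 drawn splits as many, highest other 3890) the splits cannot decide. Nor can they for the difference between the double and the Hdac3 knockout (5248, 2 of 100 drawn splits, highest other 5862). Both shares lie under 0.05, but 100 draws place such shares only roughly. These splits exchange cohorts separately within knockouts and within controls, so uneven exchanges can carry the knockout effect. For 3 against 3 libraries the splits are too few for a share under 0.05: Ncor1 (55 genes, 1 of 10 splits as many, highest other 0), Ncor2 (1, 3 of 10, highest other 1), dexamethasone in controls (824, 1 of 10, highest other 0), dexamethasone in double knockouts (184, 1 of 10, highest other 0) and the vehicle-treated double knockout (4933, 1 of 10, highest other 0). Agreement between comparisons that share no library, which a chance split does not predict, is a separate measure. The vehicle-treated and the day 5 double knockout shared 939 raised genes (197 for independent lists) and 2215 lowered ones (846), with 1 and 6 in opposite directions (r = 0.875 over all tested genes). Dexamethasone in the 2 genotypes shared 108 raised (4.55) and 27 lowered genes (1.74), with 0 opposite. The Ncor1 and the Hdac3 knockout shared 36 raised (4.83) and 5 lowered genes (1.14), with 0 and 3 opposite. For the interaction (15 genes) 6 of 100 drawn splits gave as many, so chance is not excluded. The 5 others called 478, 2092, 5985, 83 and 1460 genes, several times the real count, because they exchanged genotypes unevenly between treatments and so carry the knockout effect, a structure of the samples.

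Dexamethasone responses differed between genotypes for 15 genes, with log2 differences for Gas1 (1.639, smaller drop), S1pr5 (1.493), Gadd45b (-3.161), Fam89a (-2.428), Sgk1 (-2.37), Gdf15 (-2.304), Gadd45g (-2.151), Tgtp1 (-2.148), Mdm1 (-2.056) and Cbr3 (-1.901).

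Double knockout effects differed between day 15 and day 5 for 3309 genes. Among preselected genes the log2 differences were 0.4857 for Hdac3, -0.5924 for Nr3c1, -2.076 for G6pc, -1.635 for Fbp1, -2.424 for Tat, -3.586 for Hsd11b1, -3.562 for Fgf21, 1.496 for Cidec and -1.339 for Cyp7a1. The largest upward differences were 8.147 for Sult2a2, 7.347 for Sult2a1, 7.099 for Sprr1a, 5.423 for Maoa, 5.257 for Gipc2, 4.88 for Gpnmb, 4.635 for Apoa4 and 4.54 for H2-Q1. The largest downward ones were -8.22 for Ces3a, -7.061 for Mup3, -6.785 for Cyp2c54, -6.694 for Serpina1e, -6.486 for Car3, -5.697 for Rgn, -5.669 for Cyp2c50 and -5.458 for Cyp2c44. Whether reads were shared between copies of the Sult2a, Mup, Cyp2c, Serpina1 and H2-Q families was not tested. At day 15 the double and the Hdac3 knockout effects differed for 5248 genes.

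Single libraries stood apart in 9 of 95 gene-by-group tests, where about 1 in 20 would by chance. In Hdac3 knockout library 4, Hdac3 was 10.72 TPM (others 5.621 to 6.367), Fbp1 1141 (882.4 to 918.7) and Hsd11b1 645 (425.6 to 444.1). In day 15 control library 2, Tsc22d3 was 175.5 (63.96 to 72.18), and in control library 4 Per1 was 15.76 (22.2 to 23.49) and Cyp7a1 127.8 (64.53 to 73.52). In day 15 double knockout library 1, G6pc was 60.26 (154.7 to 159.7), and in library 4 Hsd11b1 was 28.52 (19.87 to 20.72). In day 5 control library 3, Scd1 was 2380 (1085 to 1266).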

How the results depend on the processing

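No test in this part was chosen after the result was seen except the fits without vehicle-treated knockout library 1 or Ncor1 knockout library 2. Counts that moved by more than 1.5 times belonged to the small cohorts and to Hdac3. For the Ncor1 knockout (55 genes) the count was 0 with no filter on low values (1990 at unadjusted p under 0.05), 23 with rescaled TPM, 1617 with all libraries in a single fit, 34 with a replicate block, and 3 (without control 2) to 71 (without knockout 2). For the Ncor2 knockout (1 gene) it was 3 with all libraries, 8 with a replicate block, and 0 (without knockout 1, 259 at unadjusted p under 0.05) to 5 (without knockout 3). For Hdac3 (2881) it was 1612 with all libraries and 1801 (without knockout 3) to 3153 (without knockout 4). For dexamethasone in controls (824) it was 458 (without control dexamethasone 3) to 1542 (without knockout vehicle 1), and 1465 without that library and rescaled. For dexamethasone in double knockouts (184) it was 75 (without knockout dexamethasone 2) to 249 (without knockout vehicle 2). For the interaction (15) it was 30 rescaled, 25 with all libraries, 6 (without control vehicle 2) to 23 (without knockout vehicle 2), and 34 without knockout vehicle 1 and rescaled. Of 366 gene list tests, 179 passed with the preset correlation and 2 with an estimated one. With the replicate block the other counts were 3610 (day 5), 6941 (day 15), 2533 (Hdac3), 610 and 137 (dexamethasone in controls and double knockouts), 13 (interaction), 4557 (vehicle), 3323 (days) and 5100 (double against Hdac3). The larger counts stayed within 1.5 times with any library left out: 3159 to 3843 (day 5), 6567 to 7272 (day 15), 4023 to 5020 (vehicle), 2648 to 3451 (days) and 4886 to 5310 (double against Hdac3). Without the library that stood apart and rescaled, Ncor1 gave 40, dexamethasone in double knockouts 213 and the vehicle-treated double knockout 5052. Replicate numbers did not pair the samples, as correlations of same-numbered libraries ran from -0.32 to 0.38. Of 917 called results of named genes, 141 lost the call with some library left out, 83 with no filter, 38 with the block, 32 rescaled and 23 with a pseudocount of 0.1, and 0 reversed.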

Other observations

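The genes followed across knockouts here were chosen after the values were seen, while the test of the hypothesis below was not. Of the 48 genes raised in Ncor1 knockout livers, 36 also rose in Hdac3 knockout livers (4.83 for independent lists) and 37 in the day 5 double knockout (5.62). In the day 15 double knockout 24 of them rose (12.8) and 17 fell (16.3). Ehhadh, a peroxisomal enzyme, rose in all of them, with log2 changes of 2.78 (Ncor1), 2.09 (Hdac3), 4.55 (day 5) and 5.27 (day 15). Abcb11, the bile salt export pump, rose by 1.48, 0.505 and 1.03 in the same order and fell at day 15 (-0.98). Car14, a carbonic anhydrase, rose by 2.03, 1.60 and 1.23 and fell at day 15 (-1.895), and Acss3, an acyl-CoA synthetase of mitochondria, rose by 1.80, 1.53 and 1.14 and fell at day 15 (-1.08).

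Of the 25 Kupffer cell and macrophage markers tested at day 15, 23 rose and 0 fell, and the 2 not called both mark resident Kupffer cells. Clec4f was 81.2 ± 25 against 76.05 ± 13.7 TPM (adjusted p = 0.801) and Timd4 4.18 ± 2.78 against 5.25 ± 0.351 TPM (adjusted p = 0.229, n = 4 and 4). Other markers of these cells rose: Cd5l (226.4 ± 32.8 against 90.78 ± 15 TPM, adjusted p = 1.15e-05), Marco (15.28 ± 6.2 against 6.914 ± 1.77 TPM, adjusted p = 0.00698) and Vsig4 (52.9 ± 4.4 against 28.95 ± 6.3 TPM, adjusted p = 0.00035). So did the wider macrophage markers Adgre1 (28.02 ± 5.61 against 9.87 ± 2.61 TPM, adjusted p = 5.96e-05) and Cd68 (54.6 ± 15.2 against 12.45 ± 2.8 TPM, adjusted p = 8.2e-06). Epcam, of cholangiocytes and progenitor cells, rose (9.74 ± 4.38 against 2.135 ± 1.12 TPM, adjusted p = 0.000644). Alb, the albumin gene of hepatocytes, fell (14240 ± 1930 against 53000 ± 5960 TPM, adjusted p = 3.14e-07).

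The hypothesis was that the corepressors compensate for each other, so that summed single knockout effects fall short of the double knockout effect. Over the 3995 genes called at day 5 and tested in all, signed by the day 5 direction, the median effect at day 15 was 0.691 log2 in the double knockout, 0.102 in the Ncor1 and 0.00215 in the Ncor2 knockout. The median of the summed single effects was 0.105, a ratio of 0.152 (0.13 to 0.17, bootstrap over genes) to the double knockout median, and 0.183 with rescaled TPM. The ratio lies under the bound of 0.5 set in advance, so the result fits the hypothesis. A threshold in total corepressor or less loss of the targets in the single knockouts, rather than compensation, could give the same ratio of 0.152, and the cohorts differed between knockouts.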
